A study of Mus musculus with 6 samples.

How the data were processed

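The series holds 6 RNA-seq libraries of primary dermal fibroblasts from newborn mouse skin, 3 from mice with Col1a2Cre alone (ctrl) and 3 from mice with Col1a2Cre and a constitutively active Nrf2 (caNrf2). Groups and replicate numbers were taken from the sample titles. The series' design text states that the cells of each group came from 3 mice. The sample titles give only group and replicate number, so each library was assumed to stand for a separate mouse.

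The authors deposited a table per library with 104129 Ensembl transcripts of 43629 genes. The submitters' processing notes name RSEM 1.2.21, CASAVA 1.8 and the genome build GRCm38. The aligner, the annotation release, trimming, read length and the strand setting are not given in the sources used here. Per the file headers, the deposited values are expected counts per transcript, as a maximum likelihood estimate and as a posterior mean, which need not be whole because reads that match several transcripts are divided among them. Per the file headers, each table also holds TPM, transcripts scaled by the authors to a common total per library. The deposited FPKM values, per the file headers fragments scaled by length and library size, were not used in any test. TPM was read only for the transcripts of Nfe2l2. Because RSEM divides shared reads by estimated abundance, values of close paralogs such as Gsta1 and Gsta2 are less certain than those of other genes. Without a stated strand setting, reads of overlapping or antisense genes could not be told apart.

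The maximum likelihood expected counts were summed per gene ID and rounded to whole numbers. Gene symbols came from a reference table of gene names, which named 42462 of the 43629 IDs, and 20 symbols stood on more than 1 ID. Coordinates are those of the deposited tables (GRCm38, counted from 1). Gene types, and GC content for an added correction, came from GENCODE M21 on the same build, in which 42460 of the IDs overlap their locus. Library totals were 34728233, 45164071 and 30168250 expected counts for ctrl replicates 1 to 3 and 37031932, 44925782 and 43553292 for caNrf2 replicates 1 to 3, so that a single read was worth 0.0223 to 0.0331 CPM. Every table row carried a gene ID.

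The comparison was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total count 15), TMM normalization and the two-sided quasi-likelihood F test without a replicate block, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene past that threshold is said to be called. Values per library are CPM with TMM-scaled library sizes, given as mean ± SD with n = 3. Standard errors of log2 fold changes were derived from the F statistic. The test was run on simulated counts drawn from the means, library sizes and dispersions of these libraries. Of 100 genes changed 2-fold it called 85, of 100 changed 1.5-fold it called 50, and of 14969 unchanged genes it called 7, with 15169 genes tested. The changed genes lay above a count floor and were a small share of all, while 21.5% of genes were called in the real comparison. The adjustment depends on that share, so these rates need not hold for the real comparison.

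Before the data were examined, 34 gene lists were fixed from textbook knowledge, covering NRF2 targets, extracellular matrix (ECM), SASP factors, senescence, proliferation, contractile genes, signalling and stress responses, metabolism, fibroblast subtypes, other cell types of newborn skin and RNA quality. The 33 lists with at least 3 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. A list's median and mean are those of its members' edgeR log2 fold changes. Adjusted p-values of single genes are from edgeR and those of lists from camera unless another method is named.

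The genes named in the text follow a rule fixed before the data were examined. They are Nfe2l2, 15 genes chosen by name, and the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean CPM of at least 5, non-overlapping groups and an approved symbol. For each main list the rule adds the 3 rising and 3 falling called members of smallest adjusted p. For each further list it adds 1 of each, and for cell type and quality lists the most abundant member and the called member of smallest adjusted p. Genes outside the rule are marked as chosen after their values were seen. Of the genes the rule names, 1 of those chosen by name and 1 falling member of a further list are left out of the text.

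The alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile factors, total counts, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, unrounded counts, each library left out, the replicate number as a block, small and mitochondrial RNA genes left out, an estimated inter-gene correlation, the fry rotation test and a prior count of 0.5. After the data were seen, corrections for GC content and transcript length, a fit without replicate 1 of both groups, sex inferred from Xist and Y-linked genes as a covariate, and the posterior mean counts were added. A test of transcript usage within genes (edgeR diffSpliceDGE on per-transcript counts) and a scan for neighbouring changed genes were also added after the data were seen. Genes that failed the filter were not tested. Figures were drawn with matplotlib 3.10.9.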

Results

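RNA was sequenced from primary dermal fibroblasts, the cells that make most of the collagen of the skin, after isolation from newborn mice and 6 days of culture (passage 1). All 6 mice carried Col1a2Cre, a Cre recombinase expressed in fibroblasts, on a background of 50% C57Bl/6 and 50% FVB/N. In 3 of them Cre was combined with caNrf2, a constitutively active mutant of Nrf2, the transcription factor encoded by Nfe2l2 that drives antioxidant and detoxification genes. The other 3 had Cre only and are called ctrl. The title of the series relates the comparison to the senescence-associated secretory phenotype (SASP), the cytokines, growth factors and proteases that senescent cells release. Total expected counts per library lay between 30168250 and 45164071.

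Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, GRCm38) was 3.48-fold higher in caNrf2 cultures. Its level was 109 ± 5.87 CPM in ctrl and 380 ± 43.2 CPM in caNrf2 (SD, n = 3 each), a log2 fold change of 1.8 with an SE of 0.10 (edgeR adjusted p = 5.96e-06). Nearly all of its reads were assigned to the transcript ENSMUST00000102672, at 247 to 331 TPM in caNrf2 libraries and at most 87.1 TPM in ctrl libraries. Whether these reads came from the endogenous gene or from the transgene cannot be read from counts per transcript. The other transcript, ENSMUST00000152371, held few counts, at 0.74 to 1.06 TPM in ctrl and 0.78 to 0.93 TPM in caNrf2 libraries. Transcript usage of Nfe2l2 was not called (edgeR diffSpliceDGE adjusted p = 0.0904). In CPM of the whole gene, each caNrf2 library was above each ctrl library.

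The cultures separated by genotype across the transcriptome. Of 15341 genes tested, 3302 (21.5%) were called, 1917 higher and 1385 lower in caNrf2, and the change was at least 2-fold for 805 of the higher and 254 of the lower genes. The groups did not overlap in 6459 genes (42.1%), where chance gives 10%. The first principal component held 65% of the variance of log2 CPM and placed ctrl libraries between -47.8 and -36.7 and caNrf2 libraries between 38.1 and 47.5. Across genes, which are not independent replicates, libraries of a group correlated at 0.985 to 0.993 and libraries of different groups at 0.957 to 0.972. The number of lower genes fell to 823 without ctrl replicate 3 and to 864 without caNrf2 replicate 2.

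The genes with the highest fold change were led by glutathione S-transferases, enzymes that conjugate glutathione to reactive compounds. Gsta1 went from 0.34 ± 0.251 to 226 ± 32.9 CPM, Gsta2 from 0.0538 ± 0.0221 to 34.9 ± 7.94 CPM and Gsta3 from 0.333 ± 0.163 to 168 ± 24.4 CPM (edgeR adjusted p at most 2.24e-07). Gsta1 and Gsta2 are close paralogs, so their separate values are uncertain. Also near absent in ctrl and raised in caNrf2 were Nyx (13.8 ± 2.02 CPM in caNrf2), Igfn1 (30.7 ± 4.61), the neurofilament gene Nefm (29.1 ± 4.92), Map7d2 (79.6 ± 11.1) and Brinp3 (23.3 ± 1.93). The lowest fold changes belonged to Pappa2, a protease of IGF-binding proteins (0.201-fold), Slc26a7 (0.214), Ldb2 (0.215), Trim66 (0.238), the ATP-gated channel gene P2rx3 (0.254), Clec3b (0.266), the microfibril gene Mfap4 (0.283) and Lgr5, a receptor for R-spondins (0.295). Lgr5 was the most abundant of them, at 708 ± 112 CPM in ctrl and 209 ± 46 CPM in caNrf2 (log2 fold change -1.76, SE 0.18, adjusted p = 0.000214). Clec3b was no longer called without ctrl replicate 1 (log2 fold change -1.84, adjusted p = 0.0559).

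NRF2 target genes rose almost as a whole. Of 36 tested members, 34 were higher, the same 34 adjusted over the list alone, with a median log2 fold change of 2.40. Nqo1, a quinone reductase, rose 25.3-fold from 26.1 ± 3.09 to 661 ± 78.6 CPM (SE of the log2 fold change 0.14, adjusted p = 1.38e-07). Srxn1, which restores oxidized peroxiredoxins, rose 16.1-fold (57.2 ± 4.61 to 918 ± 80 CPM, adjusted p = 1.24e-07). Both subunits of the enzyme that limits glutathione synthesis rose, Gclm 6.84-fold and Gclc 4.78-fold. Hmox1, which degrades heme, rose 1.86-fold (142 ± 17.6 to 263 ± 13.3 CPM, SE 0.10, adjusted p = 0.000487). Gsta4 rose 24-fold and the efflux transporter gene Abcc4 10.4-fold. The list was called by camera (adjusted p = 1.79e-31) but not with an estimated correlation (adjusted p = 0.26, over its 15 alternatives 2.52e-32 to 0.26). That setting called 0 lists, even this one with 34 of 36 members higher. Failing it, here and below, therefore does not tell one list from another. The 2 uncalled members of the list were Ugdh and Idh1, both chosen after their values were seen.

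**Figure D1:**
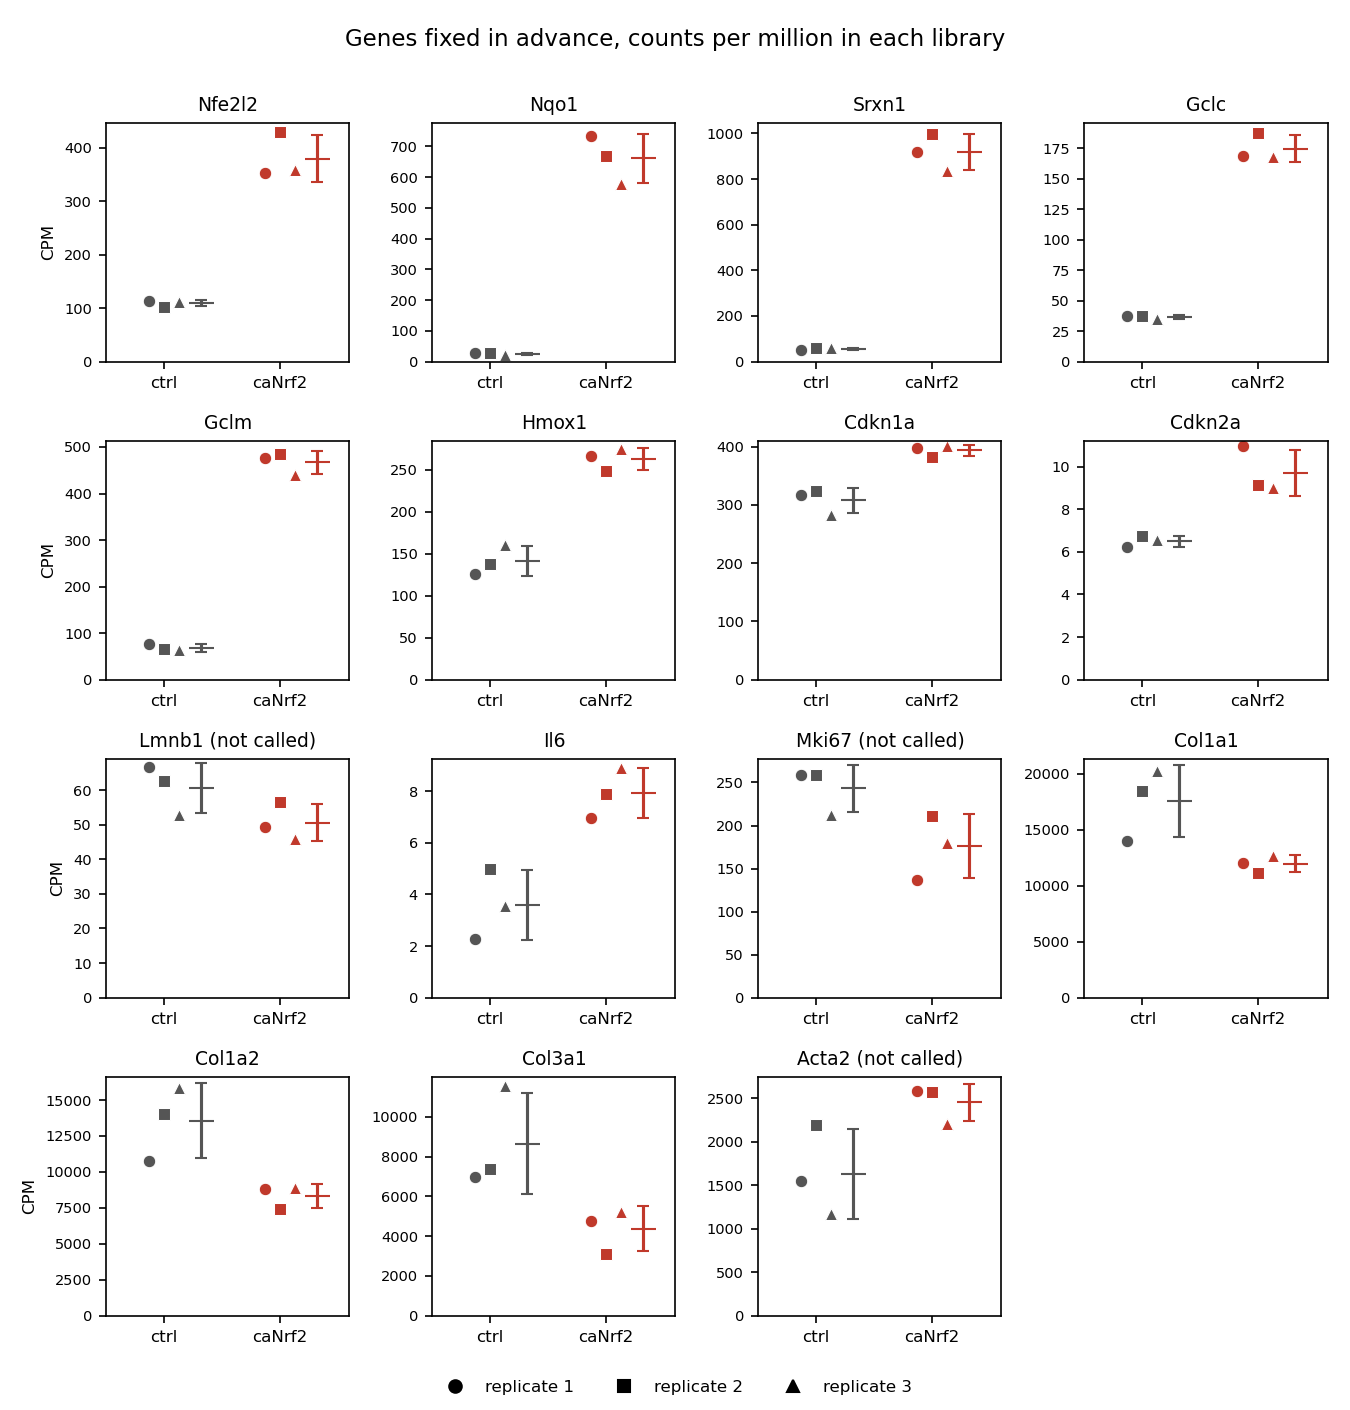
Library-size-scaled counts (CPM, vertical axes from 0) of Nfe2l2 and 14 of the 15 genes chosen by name, with a symbol for each library and the mean ± SD (n = 3) beside each group. Nqo1 averaged 26.1 CPM in ctrl and 661 CPM in caNrf2, and Lmnb1, Mki67 and Acta2 were not called.

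Major interstitial collagens and several matrix glycoproteins were lower in caNrf2 cultures, while basement membrane genes of the nidogen family were higher. Col1a1 and Col1a2, which encode the chains of type I collagen, were 0.68-fold (17603 ± 3234 to 11967 ± 762 CPM, SE of the log2 fold change 0.13, adjusted p = 0.0192) and 0.617-fold (13544 ± 2607 to 8355 ± 836 CPM, adjusted p = 0.00993). Col3a1, of type III collagen, was 0.505-fold (8643 ± 2546 to 4362 ± 1132 CPM, SE 0.24, adjusted p = 0.0184). Of 22 collagen genes tested, 7 were lower and 3 higher (10 and 3 adjusted over the list alone). Col5a1, Col8a2 and Col15a1 led those that fell and Col7a1, of the anchoring fibrils (1.65-fold), Col4a5 (1.39-fold) and Col5a3 (1.59-fold) rose. Col4a5 lost its call without ctrl replicate 2 (log2 fold change 0.49) or 3 (0.37) or caNrf2 replicate 2 (0.40) or 3 (0.47). Col5a3 lost its call without ctrl replicate 2 (0.75) or caNrf2 replicate 1 (0.70), 2 (0.69) or 3 (0.61) and kept it in only 12 of its 21 alternatives. The list as a whole was not called (median log2 fold change -0.23, adjusted p = 0.166). Col1a1 missed the threshold without ctrl replicate 2 (log2 fold change -0.52), ctrl replicate 3 (-0.45) or caNrf2 replicate 1 (-0.56), 2 (-0.52) or 3 (-0.61). Col3a1 missed it without replicate 1 of both groups (-1.20, adjusted p = 0.0503). The list passed it without ctrl replicate 1 (median -0.33, adjusted p = 0.0323, over its 15 alternatives 0.0239 to 0.764).

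Among 53 ECM glycoproteins and proteoglycans, 20 were lower and 7 higher (24 and 10 adjusted over the list alone). Aspn (0.313-fold), Fmod (0.367-fold) and Fbn2 (0.425-fold, 1432 ± 77 to 609 ± 67.6 CPM) fell, and Nid1 (2.96-fold, 803 ± 44 to 2379 ± 168 CPM), Ecm1 (2.15-fold) and Nid2 (1.84-fold) rose. The list was called lower (median -0.25, adjusted p = 0.0376) but not with an estimated correlation (adjusted p = 0.692, over its 15 alternatives 0.0121 to 0.692). It also lost its call without ctrl replicate 2 (median -0.24), ctrl replicate 3 (-0.20) or caNrf2 replicate 1 (-0.17). ECM regulators, the proteases, inhibitors and crosslinking enzymes of the matrix, moved both ways, 10 higher and 8 lower of 44 (11 and 11 adjusted over the list alone). Tgm2 (3.59-fold), Ctsb (1.91-fold) and Sulf1 (2.35-fold) rose, and Timp3 (0.461-fold), Adamts1 (0.651-fold) and Mmp14 (0.644-fold) fell. That list was not called (adjusted p = 0.806), and its median of -0.11 and mean of 0.07 differed in sign, with the test pointing lower.

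SASP factors moved in both directions with more of them higher. Of 50 tested, 19 were higher and 7 lower (21 and 9 adjusted over the list alone), 24 were not called, and the median log2 fold change was 0.31. Il11, a cytokine of the IL-6 family, rose 9.02-fold from a low level (0.473 ± 0.0989 to 4.27 ± 1.85 CPM), Plaur, the urokinase receptor gene, 2.88-fold, and Igfbp4 2.23-fold. Il6 rose 2.19-fold (3.6 ± 1.35 to 7.94 ± 0.966 CPM, SE of the log2 fold change 0.25, adjusted p = 0.0126). Angptl4 (0.557-fold), Icam1 (0.628-fold) and the chemokine gene Ccl7 (0.741-fold) fell. As a list moving in 1 direction, the SASP factors were not called by camera (adjusted p = 0.168, over its 15 alternatives 0.0706 to 0.764), nor by fry (adjusted p = 0.106). The mixed test of fry, for changes in either direction, called the list (adjusted p = 0.00017), as it did most lists. Over all tested genes 21.5% were called. Macrophage and leukocyte markers, several of whose cells release such factors, were higher in the same cultures (17 of 18, median log2 fold change 1.92).

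Senescence regulators were divided. Of 12 tested, 4 were higher and 2 lower (5 and 3 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.432). The cell cycle inhibitor genes Cdkn2b (1.97-fold, 26.8 ± 2.08 to 52.8 ± 7.29 CPM), Cdkn2a (1.49-fold, 6.51 ± 0.258 to 9.7 ± 1.09 CPM, adjusted p = 0.00993) and Cdkn1a (1.28-fold, 308 ± 21.2 to 394 ± 9.71 CPM, SE of the log2 fold change 0.08, adjusted p = 0.0177) rose, and their relatives Cdkn1b (0.597-fold) and Cdkn1c (0.462-fold) fell. Cdkn1a missed the threshold without ctrl replicate 3 (log2 fold change 0.30) or caNrf2 replicate 3 (0.33). Of 22 p53 target genes, 5 were higher, led by the death receptor gene Tnfrsf10b (1.64-fold), and 1 was lower, Sesn1 (0.699-fold), with 7 and 2 adjusted over the list alone and no call for the list (median 0.09, adjusted p = 0.241).

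Few proliferation genes were called. Of 44 tested, 3 were called by edgeR, all lower, Hmgb2 (0.762-fold), Tpx2 (0.797-fold) and Cenpf (0.735-fold), and 0 were called adjusted over the list alone. DESeq2 called 5 lower and limma-voom 3, and 8 were lower at an unadjusted p under 0.05 in edgeR. Mki67 averaged 243 ± 27.1 CPM in ctrl and 176 ± 37 CPM in caNrf2 (log2 fold change -0.47, SE 0.15, adjusted p = 0.0626), and Lmnb1, which encodes the nuclear envelope protein lamin B1, 60.7 ± 7.14 and 50.6 ± 5.36 CPM (-0.26, SE 0.11, adjusted p = 0.123). The list had a median of -0.06 (adjusted p = 0.0833). It was called lower without ctrl replicate 3 (median -0.14, adjusted p = 0.00145) or caNrf2 replicate 2 (-0.12, 0.00142), and over its 15 alternatives the adjusted p ranged from 0.00142 to 0.865. Mki67 was called lower without caNrf2 replicate 2 (log2 fold change -0.63, adjusted p = 0.0226), with DESeq2 (-0.47, 0.0127), without a filter (-0.47, 0.0183), with upper-quartile factors (-0.51, 0.04) and after the length correction (-0.37, 0.0381). Hmgb2 lost its call without caNrf2 replicate 2 (-0.42), ctrl replicate 1 (-0.29) or caNrf2 replicate 3 (-0.35). Tpx2 and Cenpf lost theirs without ctrl replicate 1 (-0.31 and -0.38), ctrl replicate 2 (-0.29 and -0.41), caNrf2 replicate 1 (-0.28 and -0.35) or caNrf2 replicate 3 (-0.31 and -0.45), and without replicate 1 of both groups (-0.25 and -0.27). After the GC correction Hmgb2, Tpx2 and Cenpf were not called (-0.23, -0.28 and -0.34).

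Contractile genes of the myofibroblast, the smooth muscle-like state of a fibroblast, were higher. Of 22 tested, 9 were higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.35. Synpo2, an actin-binding protein gene, rose 6.11-fold (9.3 ± 0.675 to 56.9 ± 8.73 CPM), Cnn1 2.89-fold and Des 1.68-fold, and the cadherin gene Cdh11 fell (0.736-fold). Acta2, which encodes smooth muscle actin, averaged 1632 ± 516 CPM in ctrl and 2451 ± 211 CPM in caNrf2 (log2 fold change 0.59, SE 0.20, adjusted p = 0.0678) in the edgeR fit. It was called with the replicate block (0.63, adjusted p = 0.0208), without a filter (0.58, 0.0159), with DESeq2 (0.58, 0.00796) and without ctrl replicate 2 (0.85, 0.00899). The list was called higher (adjusted p = 0.00227) but not with an estimated correlation (adjusted p = 0.692, over its 15 alternatives 8.93e-05 to 0.692). Skeletal muscle markers, of which Des is one, were higher in the same cultures (13 of 16, median 0.78). Of 20 TGF-beta response genes, 3 were higher and 3 lower (4 and 3 adjusted over the list alone), among them Tagln (1.76-fold) and the oxidase gene Nox4 (0.488-fold), of which Tagln lost its call without replicate 1 of both groups (log2 fold change 0.75, adjusted p = 0.0824). The TGF-beta list was not called (adjusted p = 0.95), and its median of -0.01 and mean of 0.02 lay on either side of 0, with the test pointing lower.

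**Figure D2:**
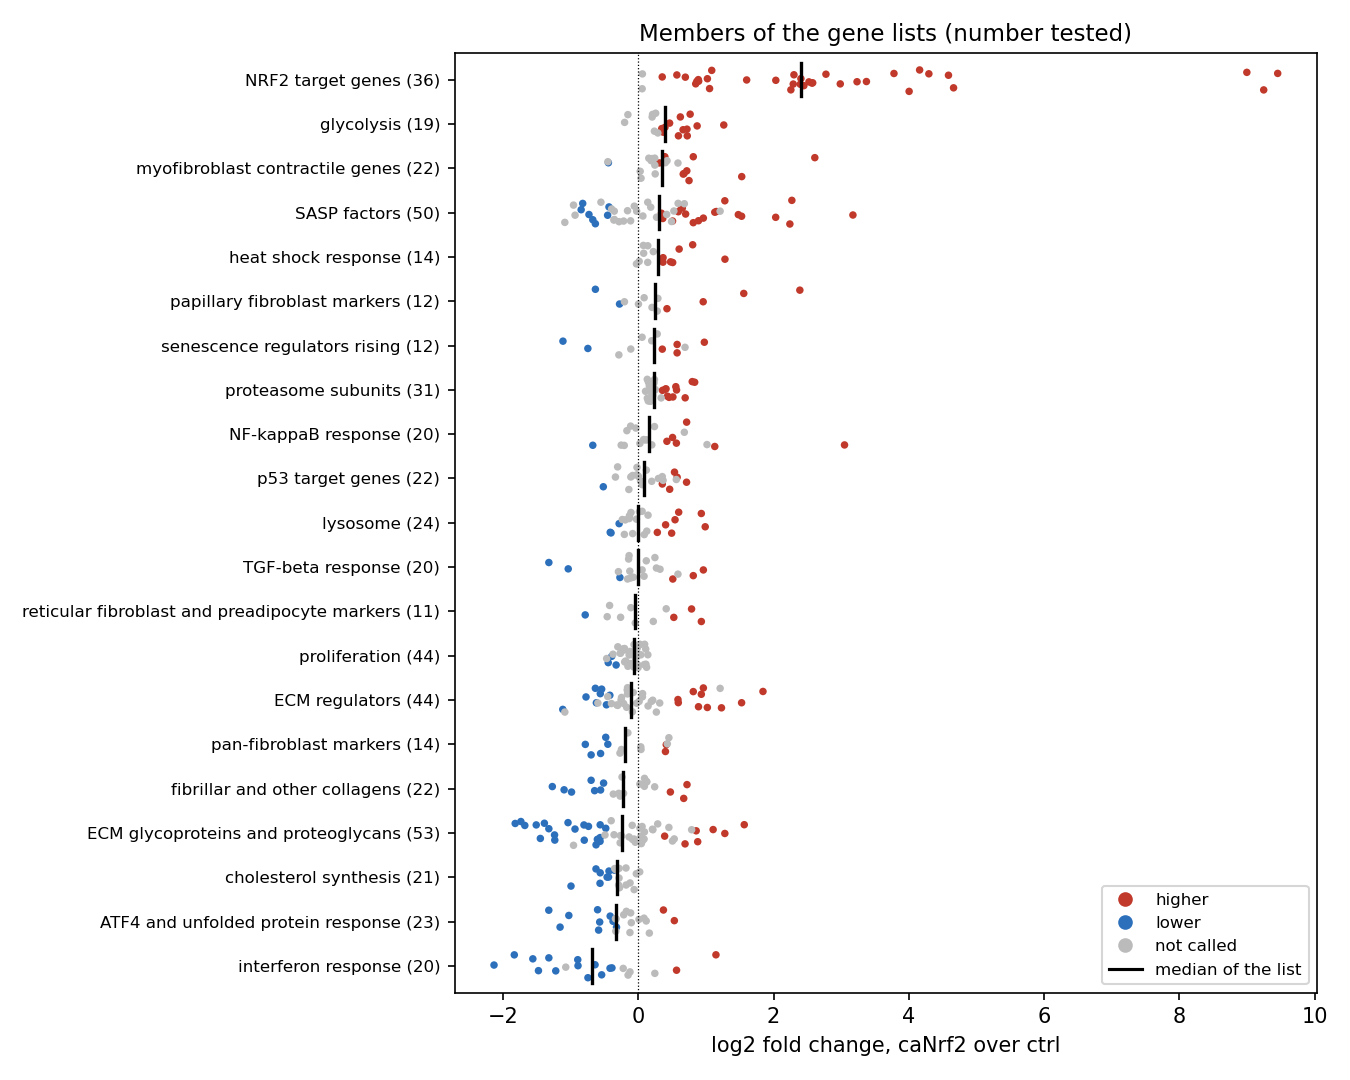
Log2 fold change (caNrf2 over ctrl, horizontal axis) of each tested member of the lists on fibroblast biology, signalling and metabolism, a point per gene, red where called higher, blue where called lower and grey where not called, with a bar at the list's median. The NRF2 target genes have a median of 2.40 and the interferon response genes of -0.69.

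Lists of glycolysis, proteasome, heat shock and cholesterol synthesis genes were called by camera with the preset correlation. None of them was called with an estimated correlation, a setting that called no list at all. Among glycolysis genes 12 of 19 were higher and 7 not called (14 higher adjusted over the list alone; median 0.40, adjusted p = 2.44e-05), led by the glucose transporter gene Slc2a1 (2.40-fold, 62.8 ± 10.8 to 151 ± 6.19 CPM). Among proteasome subunits 11 of 31 were higher and 20 not called (18 higher adjusted over the list alone; median 0.23, adjusted p = 4.23e-07), and all 31 had positive log2 fold changes, with Psmd11 at 1.78-fold. Among heat shock genes 7 of 14 were higher and 7 not called, the same counts adjusted over the list alone (median 0.29, adjusted p = 0.00262), with the small heat shock protein gene Hspb8 at 1.75-fold. Cholesterol synthesis genes went the other way, 9 of 21 lower and 12 not called (14 lower adjusted over the list alone; median -0.32, adjusted p = 5.33e-05). Insig1, which stands on the list as a regulator of that synthesis and not as an enzyme of it, was at 0.676-fold. With an estimated correlation the adjusted p was 0.692 for each of these lists, the highest over their alternatives, of which the lowest were 1.42e-06, 1.71e-07, 0.00147 and 8.78e-06 in the same order. Cholesterol synthesis was not called by fry either (adjusted p = 0.0589).

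Interferon response genes were lower. Of 20 tested, 13 were lower and 2 higher, the same counts adjusted over the list alone, with a median of -0.69. The signal transducer gene Stat2 fell to 0.539-fold (51 ± 4.51 to 27.5 ± 3.4 CPM), while the guanylate-binding protein gene Gbp2 rose 2.22-fold. Targets of ATF4 and the unfolded protein response were also lower, 9 of 23 against 2 higher (13 and 2 adjusted over the list alone; median -0.32), with Vldlr at 0.491-fold and Sdf2l1 at 1.45-fold. Both lists were called (adjusted p = 5.33e-05 and 0.0064) but not with an estimated correlation (adjusted p = 0.692 for each, over their alternatives from 1.22e-07 and 0.00109). Sdf2l1 lost its call without ctrl replicate 1 (log2 fold change 0.53) or ctrl replicate 3 (0.45), and without replicate 1 of both groups (0.42).

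NF-kappaB response genes had 6 higher and 1 lower of 20, the same counts adjusted over the list alone (median 0.17, adjusted p = 0.207), in cultures in which leukocyte markers were also higher. Ptgs2, the inducible cyclooxygenase gene, rose 8.28-fold (51.7 ± 16.7 to 428 ± 109 CPM). Lysosome genes had 7 higher and 3 lower of 24 (7 and 4 adjusted over the list alone), with the protease gene Ctsd at 1.99-fold. Their median was -0.004 and their mean 0.10, with the test pointing higher and not past the threshold (adjusted p = 0.638).

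Markers of fibroblast subtypes were mixed. Papillary markers, of the upper dermis, had 4 higher and 2 lower of 12 (5 and 2 adjusted over the list alone; median 0.24, adjusted p = 0.166), with the Wnt agonist gene Rspo1 up 5.24-fold and Crabp1 at 0.645-fold. Reticular and preadipocyte markers had 3 higher and 1 lower of 11, the same adjusted over the list alone, with Cd36 at 1.91-fold and Pparg at 0.581-fold (adjusted p of the list 0.926, median -0.04, mean 0.07, test pointing higher). Pan-fibroblast markers had 2 higher and 5 lower of 14, the same adjusted over the list alone (median -0.20, adjusted p = 0.345), with Pdgfra at 1.33-fold and Twist1 at 0.581-fold. Pdgfra lost its call without ctrl replicate 2 (log2 fold change 0.36) or caNrf2 replicate 3 (0.37).

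Markers of several other skin cell types were higher in caNrf2 cultures. Macrophage and leukocyte markers rose in 17 of 18 cases, the same adjusted over the list alone (median 1.92, adjusted p = 7.07e-08), with the lysozyme gene Lyz2 from 26.5 ± 14 to 97.6 ± 9.82 CPM and Ms4a7 up 5.75-fold. Skeletal muscle markers rose in 13 of 16 cases (14 adjusted over the list alone; median 0.78, adjusted p = 4.62e-08), with the myosin gene Myh3 from 47.3 ± 0.839 to 75.1 ± 13.1 CPM and Mylpf up 1.87-fold. Keratinocyte markers rose in 4 of 20 cases (6 adjusted over the list alone; median 0.55, adjusted p = 0.00503), with Sfn up 3.44-fold and Krt5 at 86.4 ± 24.5 and 135 ± 36 CPM (adjusted p = 0.0791). The mean log2 CPM of the keratinocyte list overlapped between groups, at 3.1 in ctrl replicate 1 and 2.86 in caNrf2 replicate 1. Melanocyte and Schwann cell markers rose in 4 of 16 cases, the same adjusted over the list alone (median 0.44, adjusted p = 0.00829), with the endothelin receptor gene Ednrb up 4.35-fold. The called shares of the keratinocyte list and of the melanocyte and Schwann cell list were near the 21.5% called over all tested genes. With an estimated correlation none of these lists was called (adjusted p = 0.692, and 0.752 for keratinocytes, the highest over their alternatives, of which the lowest were 4.56e-11, 1.51e-10, 7.75e-09 and 0.000613 in the order given). The keratinocyte list also lost its call without ctrl replicate 2 (median 0.42), and Krt5 was called without ctrl replicate 1 (log2 fold change 0.89) or caNrf2 replicate 1 (0.84), without replicate 1 of both groups (1.09) and without a filter (0.64).

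Endothelial markers had 1 higher of 14, Cdh5 (2.05-fold), the same adjusted over the list alone, while Flt1 was at 19.3 ± 2.65 and 21.7 ± 3.35 CPM (median 0.36, adjusted p of the list 0.29). Cdh5 lost its call without caNrf2 replicate 2 (log2 fold change 0.93). Pericyte and vascular smooth muscle markers had 2 higher and 2 lower of 10 (3 and 2 adjusted over the list alone; median -0.10, adjusted p = 0.638), with Abcc9 at 0.427-fold and Cspg4 at 106 ± 18.1 and 88.4 ± 16.9 CPM. Adipocyte markers had 1 lower of 8, Pparg, the same adjusted over the list alone, and Fabp4 stood at 32 ± 7.75 and 23.4 ± 9.83 CPM. Their median of 0.06 and mean of 0.33 were positive where the test pointed lower (adjusted p = 0.638), and Fabp4 was called without caNrf2 replicate 1 (log2 fold change -0.86). Only 2 mast cell markers passed the filter, too few for a list test, and Kit was 2.19-fold higher. Kit lost its call without ctrl replicate 1 (0.97), ctrl replicate 2 (1.02), caNrf2 replicate 2 (1.12) or caNrf2 replicate 3 (1.11), and without replicate 1 of both groups (0.99).

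**Figure D3:**
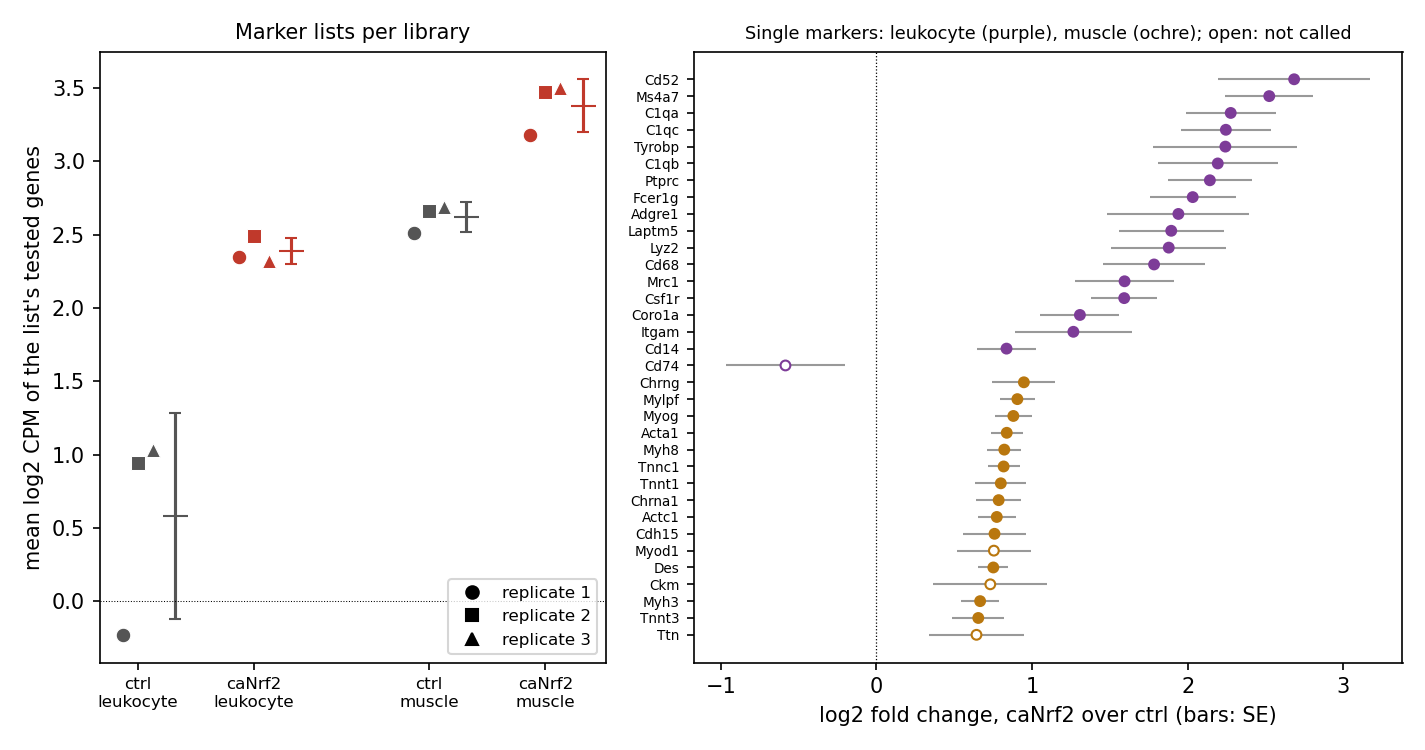
Left, mean log2 CPM (vertical axis) of the leukocyte and skeletal muscle marker lists in each library, with mean ± SD (n = 3) beside each group. Right, log2 fold change (caNrf2 over ctrl) of each tested marker with its SE, open where not called; ctrl replicate 1 had the lowest leukocyte mean, -0.23, and the caNrf2 libraries lay between 2.32 and 2.49.

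Among genes that report on RNA quality and handling, the mitochondrial and ribosomal lists were not called, and the immediate early list was. Mitochondrially encoded genes had 0 called of 13 by edgeR (median -0.09, adjusted p of the list 0.432), with mt-Co1 at 7157 ± 741 and 6722 ± 266 CPM, and cytosolic ribosomal protein genes 0 called of 38 (median -0.001, adjusted p = 0.493), with Rplp0 at 1996 ± 128 and 1811 ± 167 CPM. In each of these lists 1 gene was lower at an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 0 mitochondrial genes and 1 ribosomal protein gene, lower. The ribosomal list was called lower without caNrf2 replicate 1 (median -0.15, adjusted p = 0.000702), without replicate 1 of both groups (-0.15, 0.00105) and after the length correction (-0.05, 0.0497), and over its 15 alternatives the adjusted p ranged from 0.000702 to 0.961. Replication-dependent histones had 1 higher of 5, Hist1h2bc (2.02-fold), the same adjusted over the list alone, with Hist1h1c at 41.1 ± 5.83 and 44.8 ± 6.68 CPM (median 0.12, adjusted p = 0.806). Immediate early genes, which respond within minutes to stimulation, had 4 higher and 1 lower of 17 (5 and 2 adjusted over the list alone), with Dusp1 from 75.6 ± 2.28 to 136 ± 12.1 CPM and Egr1 at 423 ± 177 and 452 ± 18.1 CPM. That list was just called (median 0.39, adjusted p = 0.0466) but not with an estimated correlation (adjusted p = 0.764, over its 15 alternatives 0.00837 to 0.764). It also lost its call without ctrl replicate 1 (median 0.22), caNrf2 replicate 1 (0.41) or caNrf2 replicate 2 (0.38), without replicate 1 of both groups (0.22), after the GC or length correction (0.38 and 0.40) and with fry (adjusted p = 0.246).

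Sex-linked genes separated replicate 1 of each group from the other cultures. Xist, expressed from the inactive X chromosome of females, stood at 1650 CPM in ctrl replicate 1 and 813 CPM in caNrf2 replicate 1 and at no more than 1.06 CPM elsewhere, while the Y-linked Ddx3y, chosen after its values were seen, stood at 108 to 111 CPM in replicates 2 and 3. Each group thus held 1 library with the female pattern and 2 with the male pattern. No sex-linked gene was called by edgeR, DESeq2 or limma-voom, or had an unadjusted p under 0.05 in edgeR (0 of 5; adjusted p of the list by camera 0.976), and the median and mean log2 fold changes were -0.06 and -0.22. Xist itself had an adjusted p of 0.816 and took the opposite sign without ctrl replicate 1 (8.89). With the replicate block, which sets the female cultures against each other, Xist was called lower (log2 fold change -0.95, adjusted p = 0.0451). That call rests on 1 female library per group, so no spread between female replicates stands behind it. The replicate 1 libraries also scored highest on the second principal component, 25.9 and 31.2 against -19.6 to -8.9 elsewhere, and without X and Y genes they still stood apart, 16.6 and 30.1 against -17.2 to -1.5.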

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

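The corrections for GC content and transcript length, the fit without replicate 1 of both groups, sex as a covariate and posterior mean counts were chosen after the data were seen, and the other alternatives before. The call of Nfe2l2 held in each alternative run (log2 fold change 1.69 to 1.87), and none of the 3302 called genes changed sign except 2 with posterior mean counts. The total called ran from 2206 without caNrf2 replicate 2 to 3812 with the length correction, and with upper-quartile factors 1744 genes were higher and 1750 lower. Without replicate 1 of both groups the counts were 1829 and 1252. Of 108 named genes besides Nfe2l2, 84 kept call and sign in each alternative run. Leaving out a library takes the number of lower genes to between 823 and 1143, with fewer samples per fit. Depth sets a floor of 0.0223 to 0.0331 CPM for a single read.

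With an estimated correlation 0 lists were higher and 0 lower. That setting changes more of the test than the correlation alone, so the loss cannot be credited to each list's own correlation. The medians of the NRF2 targets (2.40), ECM glycoproteins (-0.245) and contractile genes (0.353) come from the edgeR fit. They do not depend on that setting and could not move with it. With fry 1 list was lower, and ECM glycoproteins (-0.245), contractile genes (0.353), ATF4 targets, cholesterol synthesis, keratinocyte and immediate early lists (adjusted p = 0.121, 0.0667, 0.0589, 0.0589, 0.246 and 0.246) were not called, while papillary markers were (0.0289). ECM regulators changed test direction with fry (median -0.109), and collagens were called after the GC correction (-0.235). The cause of these changes was not tested. With a library left out, medians ranged from -0.325 to -0.155 for collagens, -0.251 to -0.172 for ECM glycoproteins, -0.152 to -0.045 for ECM regulators, where the test turned higher without ctrl replicate 2 (-0.117), and -0.135 to -0.016 for proliferation. They ranged from 0.155 to 0.377 for SASP factors and 0.197 to 0.492 for contractile genes. For melanocyte and Schwann cell markers the range was 0.258 to 0.482, and for endothelial markers 0.101 to 0.45.

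The results that changed sign were not called where they did so. Left-out ranges were -0.228 to 0.315 for Egr1, -0.005 to 0.231 for Hist1h1c, -10.636 to 8.891 for Xist, -0.100 to 0.045 for the TGF-beta list, -0.154 to 0.075 for reticular, -0.370 to 0.263 for adipocyte, -0.154 to 0.077 for ribosomal and -0.623 to 0.519 for sex-linked genes. Without replicate 1 of both groups the values were -0.190 for Egr1, -0.099 for Hist1h1c and -0.171 for the reticular list, which stood at 0.010 after the length correction. After the GC correction mt-Co1 was at 0.053 and the mitochondrial list at 0.070. The test of sex-linked genes also turned with fry (-0.059), a prior count of 0.5 (-0.059), the block (-0.035) and sex as a covariate (-0.034). Besides these, 61 values of named genes fell short of the threshold and 15 passed it, and 22 and 4 values of further lists did so.

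A check of whether replicate numbers pair the libraries gave residual correlations of 0.214, 0.209 and 0.095 between equal numbers and -0.242 to 0.112 between unequal numbers. The third fell just short of 0.1, the minimum used, so the numbers were not taken as pairs. Even so, 5 of the 6 libraries correlated best with the library of their own number in the other group. Shared structure by replicate number is therefore not excluded. With the number as a block 1888 genes were higher and 1330 lower.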

Other observations

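The genes in these first paragraphs were chosen after their values were seen, as were the tests on markers of other cell types, the corrections for GC content and transcript length, the count on chromosome 13 and the test of transcript usage. The genome-wide scan of neighbouring genes was added after the data were seen, with its prediction written before its result.

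Several genes outside the lists rose strongly. Prdx6, a peroxiredoxin gene, rose from 186 ± 5.81 to 1752 ± 121 CPM (SD, n = 3 each), the prostaglandin reductase gene Ptgr1 from 50.1 ± 2.66 to 597 ± 59.8 CPM, and Heph, which encodes a ferroxidase of iron export, from 30.7 ± 2.04 to 476 ± 49.5 CPM. Gbe1, of glycogen branching, rose from 10.3 ± 0.499 to 132 ± 6.49 CPM, and Procr, which encodes the receptor of protein C, from 4.2 ± 0.386 to 136 ± 14.1 CPM. Some secreted factors outside the SASP list, not tested as a set, rose too, the cytokine genes Il7 (0.7 ± 0.148 to 21.6 ± 1.59 CPM) and Il1f9 (1.34 ± 0.2 to 32.9 ± 2.77 CPM) and the protease inhibitor gene Slpi (2.04 ± 0.387 to 81 ± 15.1 CPM). Each of these 8 genes had an edgeR adjusted p of at most 3.09e-07, the value of Slpi.

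Other genes outside the lists fell. Aldh1l2, a mitochondrial folate enzyme gene, fell from 388 ± 70 to 155 ± 31.2 CPM (edgeR adjusted p = 0.000784), and Pck2, a mitochondrial carboxykinase gene, from 210 ± 20.6 to 105 ± 16.8 CPM (adjusted p = 0.000884). Txnip, which encodes an inhibitor of thioredoxin, fell from 63.5 ± 10.2 to 33.1 ± 3.06 CPM, the selenium carrier gene Selenop from 159 ± 17.3 to 83 ± 12.6 CPM, and Gas6, a ligand of receptor kinases, from 315 ± 45.5 to 168 ± 21 CPM. The products of Selenop and Gas6 are secreted, so secreted factors outside the SASP list moved both ways.

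Leukocyte and skeletal muscle markers were higher in caNrf2 cultures, with medians of 1.92 and 0.78. A lower share of fibroblast RNA would raise both lists alike, and the leukocyte list rose by 1.04 more than the muscle list (SE 0.36). This comparison was chosen after the differing medians were seen and rests on few libraries. It therefore cannot decide whether a lower share of fibroblast RNA was the whole cause. All 18 tested leukocyte markers, Cd74 included, were lowest in ctrl replicate 1 among the ctrl libraries, which may reflect RNA from cells whose number differs between cultures. The muscle markers moved together (SD of their log2 fold changes 0.09, 13 called), as more RNA from muscle cells could give. Expression of these markers within the fibroblasts was not tested and stays open, as does an effect of caNrf2 on which cells persist in culture.

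Whole lists shifted up or down, and log2 fold changes rose with GC content across genes (Spearman 0.2, with medians from -0.114 to 0.098 over 5 classes of genes of equal size) and fell with transcript length (-0.1). After a correction within each library for GC content, 13 of the 14 called lists stayed called in the same direction, and after a correction for length also 13, which argues against either trend as the cause of those lists. The immediate early genes lost their call in both, from an adjusted p of 0.0466. The genotype named by the design stays open, as does RNA from other cell types for the marker lists among the 14, and a batch that follows the groups could not be tested since the labels give none.

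Changed genes lay close together in places. The window of 15 neighbours with the most changed genes held 13, on chromosome 13 from 31556134 to 33988465, with 12 higher and 1 lower (permutation p = 0.0065), and all 7 Serpinb genes in it were higher, among them Serpinb9b (6.06 ± 1.61 to 354 ± 56.5 CPM). With 1 gene kept per family and 2 Mb, the genome-wide maximum moved to chromosome 6, from 57580992 to 65144908, where 8 genes were higher and 4 lower (permutation p = 0.051), so whether a chromosomal segment contributes there stays open. The highest count left on chromosome 13 after thinning, a statistic chosen after that value was seen, had a permutation p of 0.91 against genome-wide maxima, which excludes nothing. In the chromosome 13 window 6 of the 8 genes outside the Serpinb family were called as well. Because the window was picked for its many called genes, this count decides nothing, and a segment stays open there too.

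Of the 10 ways to divide the 6 libraries into 3 and 3, only 1, the real division, gave as many as 3302 called genes, and the highest of the others gave 3. Each other division mixes the genotypes, which widens the spread within its groups, so few calls there say little about chance. In addition, 10 divisions are too few for a share under 0.05. In transcript usage within genes, tested on 38049 transcripts of 7992 genes with counts that carry no inferential replicates, edgeR called 97 genes, 31 of which also changed in total, with 654 at an unadjusted p under 0.05 and Mrto4 leading (adjusted p = 6.38e-09). Over all genes tested in total, 21.5% were called, and whether the overlap exceeds that share was not tested.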
